A study of Mus musculus with 2 samples.

How the data were processed

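Tumour-infiltrating immune cells of mice carrying B16-F0 melanoma, a transplantable mouse melanoma line, had been stained with the viability dye DAPI and sorted as CD45+ DAPI- cells before loading, per the series design. The labels name the cell type as tumour-infiltrating regulatory T (Treg) cells, but the stated sort selects all living CD45+ leukocytes. The series held 2 libraries, 1 from a wild-type and 1 from a knockout genotype, so each group held 1 sample. The labels do not name the gene that was knocked out, so its level could not be used to check the genotype labels and no gene is treated as the target.

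Libraries were made with the 10x Genomics Chromium single-cell 3' v3.1 chemistry per the labels, which captures polyadenylated RNA near its 3' end and tags each molecule with a unique molecular identifier (UMI). The authors deposited UMI counts per gene and cell barcode as whole numbers with no normalization. Cell Ranger and STAR on the mm10 mouse genome are named per the submitters' processing notes, and the matrix headers give version 5.0.0. The annotation release used for counting is not given in the sources used here. A 3' assay counts reads near the polyadenylation site, so a deletion elsewhere in a gene can leave its count unaffected. Coordinates are GRCm38, the assembly also called mm10, from a GENCODE annotation matched by gene identifier, which placed 32235 of the 32285 features.

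The matrices held 11432 wild-type and 11398 knockout barcodes. Cells with at least 500 genes, at least 1000 UMIs and a mitochondrial UMI share of at most 10% were kept, 11153 and 11131 cells. Doublets were scored per library with Scrublet in scanpy 1.11.5 at an expected rate of 0.008 per 1000 barcodes, 9.15% and 9.12%. In the wild-type library 440 cells (3.95%) were called and removed. In the knockout library only 1 cell (0.00898%) was called, below the preset minimum of 0.5%, so the caller had not worked and the 1015 cells with the highest scores, the expected share, were removed. This left 10713 wild-type cells with 94.3% of the library's UMIs and 10116 knockout cells with 80.0%. Unequal removal can move shares of large cells, so both a common rule and no removal were tried.

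Both libraries were clustered together on log-normalised counts of 2000 variable genes, 30 principal components and 15 neighbours with the Leiden algorithm at resolution 1 in igraph 0.11.9, with scikit-learn 1.9.0. No batch correction was used because library and genotype cannot be separated. T and NK cells were then clustered again in the same way. Clusters were named from preset markers where at least 3 were detected, each in at least 10% of cells, a detection level set after the data were seen, and names end in -like. A cluster with 0.719% of wild-type and 0.188% of knockout cells was set aside as mixed. It lay among the T and NK cells but was led by Igkc, Mzb1 and Iglc2 and took the B-cell name, at a median of 18191 UMIs. Whether it held doublets of T and B cells was not tested. Proliferating T and NK cells, 667 in all, took the lineage of the nearest class, which for non-proliferating cells gave back the cluster name in 61.5% of CD4 conventional-like to 94.5% of NK-like cells.

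For each class and library UMIs were summed over cells and scaled by the class sum to CPM, so that every class and library had the same total. Ratios are log2 of knockout over wild-type CPM, with exact conditional binomial 95% intervals. Shares carry exact Clopper-Pearson 95% intervals. With 1 library per genotype no test was made and no p-value is given, and every interval covers counting error only. Cells within a library are not replicates. Classes were compared where both libraries held at least 100 cells, which left out neutrophil-like cells and with them the list of neutrophil activation genes. A library at 0 was given a floor of 3 UMIs for its class sum.

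A gene counted as higher or lower when its ratio was at least 1.5-fold with an interval excluding 1, a rule of size and not a test. Gene lists, 34 in number, covered Treg identity, T-cell states, cytotoxicity, stress, interferon responses, antigen presentation, proliferation, metabolism, myeloid states and the RNA of other cell types. Members were measured at 20 UMIs or more over both libraries. Each list's median ratio was placed among 10000 random lists of the same size, drawn from 20 bins of mean CPM. The percentile describes these libraries only.

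Genes were named by a rule. A gene needed at least 50 UMIs in the class, at least 20 CPM in the higher library, and there at least 0.1 of the CPM of the class where it was highest. Mitochondrial, ribosomal protein, haemoglobin, immunoglobulin, T-cell receptor segment, clone-named, Y-linked and X-inactivation genes were excluded. Genes were ranked by the interval bound nearest to 0, and the first 12 each way were taken in Treg-like cells and the first 6 each way in other classes, plus up to 4 members of each list. The groups, filters, classes, lists, naming rule and most alternatives were fixed before the data were examined. Lists are given singly where their median lay outside the middle 95% of random lists and was at least 0.2 in size, or for the Treg lists, the cytotoxic list of CD8-like cells and the leading lists of a class, and otherwise in the class of their lowest and highest median, a choice made after the data were seen. Mx1 was not among the features. Single values of some genes that the rule named are not reported here.

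To compare shares of cells with a UMI, each cell was thinned to 1500 UMIs and shallower cells were left out. Alternatives covered looser and stricter cell filters, no doublet removal, resolution 0.5 and 2, separate clustering, clustering without the listed and marker genes, a gate on single cells, TMM factors from edgeR 4.0.16 in R 4.3.3, CPM without mitochondrial and ribosomal protein genes, means of per-cell CPM, thinned cells, subtraction of free RNA, and other minimum counts. Free RNA was estimated as the library's mean profile, scaled so that the median preset gene of other cell types reached 0. Added after the data were seen were 1 common doublet rule, shares without B-like, naive T-like and pDC-like cells, and comparisons of naive T-like and gamma-delta-like cells, which, like the lists of CD8-like cells, were repeated without proliferating or melanoma-bearing cells in doubt.

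The comparison was tested on simulated data drawn from the real class totals, with 200 genes shifted 2-fold. The size rule recovered 92.5% of them in Treg-like cells among 8709 genes, and from 84% in B-like (9005 genes) to 98.5% in macrophage-like cells (11362 genes). Intervals held the true ratio for 95.3% to 96.0% of genes across the 8 classes, and 0.564% to 1.94% of unchanged genes passed the size rule. The simulated counts carried counting error only, the error that the intervals assume, with no spread between cells. So they check the calculation, and not how often real intervals hold or unchanged genes pass in these data. Other work used python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.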

Results

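The data were UMI counts of single CD45+ DAPI- cells sorted from B16-F0 tumours of wild-type and knockout mice, 1 library per genotype. The wild-type library held 98438084 UMIs over 11432 barcodes and the knockout library 112544655 over 11398. After filtering, 10713 wild-type cells had a median of 4994 UMIs and 1641 genes, and 10116 knockout cells a median of 5918 UMIs and 1866 genes. No difference between the genotypes has a replicate check, and all intervals in brackets are 95% and cover counting error only. The knocked-out gene is not named in the labels, so the knockout itself could not be checked in the counts.

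The first comparison asked how the sorted CD45+ cells divided into classes in each genotype. B-like cells, marked by Cd79a, Ms4a1 and Ighd, made up 32.7% [31.8, 33.6] of the wild-type and 3.96% [3.59, 4.36] of the knockout library, a log2 ratio of -3.05 [-3.20, -2.90]. Most T-cell classes, NK-like cells and monocyte-like cells took larger shares in the knockout library. CD8-like cells were 9.21% [8.67, 9.78] of the wild-type and 18.7% [18.0, 19.5] of the knockout library (log2 1.02 [0.91, 1.14]), CD4 conventional-like cells 5.01% and 10.5% (log2 1.06 [0.91, 1.21]), and NK-like cells 12.3% and 22.5% (log2 0.88 [0.78, 0.97]). Treg-like cells were 2.61% [2.32, 2.93] of the wild-type and 5.90% [5.45, 6.38] of the knockout library (log2 1.18 [0.97, 1.39]).

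Naive T-like cells, marked by Ccr7 and Lef1, were lower in the knockout library at 3.61% against 6.55% (log2 -0.86 [-1.05, -0.68]), as were plasmacytoid dendritic (pDC-like) cells at 1.33% against 2.20% (log2 -0.72 [-1.04, -0.41]) and neutrophil-like cells at 0.366% against 2.24% (log2 -2.61 [-3.16, -2.11]). Monocyte-like cells had a log2 share ratio of 0.62 [0.48, 0.77], gamma-delta-like cells 0.42 [0.28, 0.57] and conventional dendritic cDC2-like cells 0.40 [0.19, 0.62]. Macrophage-like cells (-0.06 [-0.21, 0.08]), cDC1-like cells (0.08 [-0.21, 0.36]) and mature DC-like cells (-0.21 [-0.71, 0.29]) had intervals that included 0. With 1 doublet rule for both libraries, or with no doublet removal, macrophage-like cells instead took a larger share in the knockout library, beyond this interval. Plasma-like cells numbered 9 and 25. Shares sum to a whole, so the difference in B-like cells moves every other share. Without B-like, naive T-like and pDC-like cells, a denominator chosen after the data were seen, the log2 ratio was 0.54 [0.33, 0.75] for Treg-like, 0.38 [0.27, 0.50] for CD8-like, -0.02 [-0.16, 0.13] for monocyte-like and -0.70 [-0.85, -0.56] for macrophage-like cells. The same denominator turned gamma-delta-like cells (-0.22) and cDC2-like cells (-0.23), and separate clustering gave -0.87 for monocyte-like and 2.54 for macrophage-like cells.

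**Figure D1:**
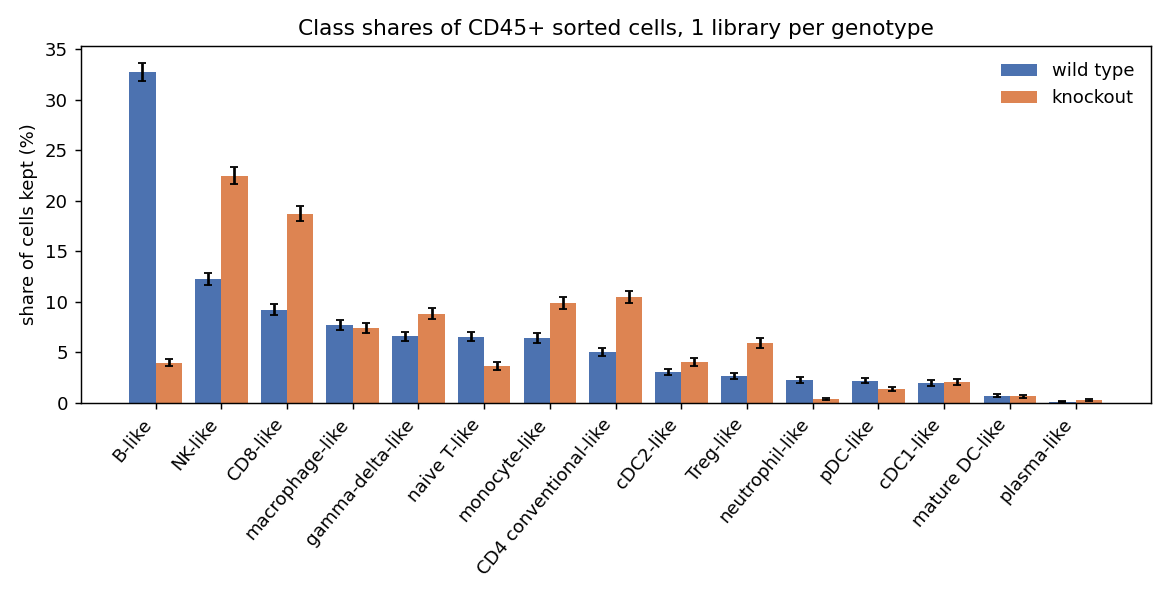
Share of cells kept (%, bars with exact 95% binomial intervals) of each class of CD45+ DAPI- sorted cells in the wild-type and the knockout library. B-like cells were 32.7% of the wild-type and 3.96% of the knockout library, while NK-like, CD8-like, CD4 conventional-like and Treg-like cells took larger shares in the knockout library.

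Within T cells, Treg-like cells made up 8.73% [7.77, 9.76] of the wild-type and 12.4% [11.5, 13.4] of the knockout T cells (log2 0.51 [0.30, 0.72]), CD8-like cells 30.8% and 39.4%, and naive T-like cells 21.9% and 7.60%. The number of CD8-like cells per Treg-like cell was 3.52 in the wild-type and 3.17 in the knockout library, a fold of 0.900 [0.763, 1.06]. As a log2 ratio, this number was -0.95 with separate clustering and 0.45 under a gate on single cells. Because Foxp3, which differed between the libraries, helps to define the class, clustering was repeated without the marker and listed genes, and the Treg-like share of T cells then had a log2 ratio of 0.44. The gate, which takes T cells with a Foxp3 UMI as Treg-like, turned the direction of that share, to -0.51.

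The main comparison was between knockout and wild-type Treg-like cells, 280 wild-type and 597 knockout cells, with 2867012 and 6383463 UMIs. Foxp3, the transcription factor that defines the Treg lineage (chromosome X, 7573644 to 7595245, ENSMUSG00000039521), was lower in the knockout library, at 211 UMIs or 33.1 CPM against 429 UMIs or 149.6 CPM, a log2 ratio of -2.18 [-2.42, -1.94]. Other Treg genes lay closer to 0, since Il2ra, the high-affinity IL-2 receptor chain, stood at -0.10, the inhibitory receptor Ctla4 at -0.07 and the transcription factor Ikzf2 at -0.08. With the marker and listed genes left out of clustering the Foxp3 ratio was -2.15. In knockout Treg-like cells 6 of 17 genes of the type I interferon response were higher, and 2 of 14 genes of resting and central T cells, among them the transcription factor Klf2, were lower.

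After thinning, 25.1% of 271 wild-type and 8.13% of 578 knockout Treg-like cells held a Foxp3 UMI, with 9 and 19 shallower cells left out, and 53.2% and 26.3% did unthinned. In B-like cells, which should lack Foxp3, the thinned shares were 0.0286% of 3491 and 0 of 399 cells, which by the floor of 3 counts allows up to 0.752%. Median depths were 6126 and 5834 UMIs in Treg-like and 3322 and 3396 in B-like cells, of which 16 and 2 were left out. Over all T cells the thinned shares were 2.35% and 1.20%, unthinned 5.30% and 3.73%, with 16 and 38 cells left out and median depths of 5784 and 5476. Thinned shares of Treg-like cells with a Ctla4 UMI were 50.9% and 45.8%, with an Ikzf2 UMI 70.1% and 70.2%, and with a UMI of the proliferation gene Mki67 14.0% and 12.8%. Unthinned, these shares were 83.6% and 83.4%, 89.3% and 89.3%, and 32.5% and 32.0%. In B-like cells, as a background, thinned shares were 0.401% and 0.251% for Ctla4 and 0.344% and 0.752% for Ikzf2. Naive T-like cells, as a background for Mki67, had 0.712% and 0.549% at median depths of 6883 and 7135 UMIs. Ifng was found in 6.27% and 4.33% of thinned and 18.2% and 20.8% of unthinned Treg-like cells, against 0.258% of wild-type and no knockout B-like cells.

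Of 18 measured genes of Treg identity and suppression, 0 were higher and 3 lower, namely Foxp3, the integrin Itgae (-1.01) and the inhibitory receptor Tigit (-0.66), with a list median of -0.13 (percentile 0.37). Gzmb stood at -0.41. In the effector Treg list, median -0.04 (percentile 12.03), the IL-33 receptor Il1rl1 was higher (0.72) and Irf4 lower (-0.74) among 18 measured. Of 14 resting and central T-cell genes 2 were lower, among them Klf2 (-0.68), and the list median was -0.27 (percentile 0.01). Of 17 type I interferon genes 6 were higher and 0 lower, median 0.47 (percentile 100), led by Ifit3 (2.97 [2.13, 3.94]), Ifit3b (2.02), Rsad2 (1.71) and Ifit1 (1.36). Ifit3 had a UMI in 3.93% of wild-type and 11.9% of knockout cells, and Ifit1 in 12.9% and 18.6%. In the knockout library 1 cell held 20.6% of the Ifit3 UMIs, and 27.8% of the Ifit1 UMIs came from 1 cell. The T-cell receptor early response had 4 of 14 higher and 1 lower, median 0.28 (percentile 99.97), including the activation-induced factors Egr3 (1.59) and Nr4a3 (1.45). Cholesterol and fatty acid synthesis genes had a median of 0.25 (percentile 99.98) with none of 20 past the size rule, for example Cyp51 at 0.57 and Insig1 at 0.55.

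Of 6 type 2 and type 17 helper genes 2 were higher, Il13 (2.93) and Il1rl1, median 0.43 (percentile 99.92), but Il13 UMIs came from 3 wild-type and 3 knockout cells and 59.9% of the knockout UMIs from 1 cell. The type 1 helper list had a median of 0.03 with Cxcr6, a chemokine receptor, higher (0.98 [0.71, 1.27]). In the inhibitory receptor list, median -0.07 with a mean of opposite sign, 4 of 17 genes were higher and 3 lower; Pdcd1, which encodes PD-1, was higher (0.86 [0.64, 1.08]) and Cd244a lower (-1.40). Further genes higher in knockout Treg-like cells were Igfbp7 (1.79 [1.25, 2.37]), Dapl1 (1.53, in 3 wild-type and 12 knockout cells, with 57.7% of the wild-type UMIs in 1 cell), Prxl2a (1.24) and the small nucleolar RNA host gene Snhg3 (1.15). Lower were the aspartic protease cathepsin E, Ctse (-2.00 [-2.38, -1.62]), the mitochondrial calcium uniporter subunit Mcub (-1.85), Rrn3 (-1.20), Rpgrip1 (-1.14), Lamtor3 (-1.12) and the heat shock gene Hspa1a (-1.09). Gzmc was lower (-3.59), but 74.7% of its wild-type UMIs came from 1 cell. Tpm3-rs7 (2.21), Nutf2-ps1 (1.22) and the histone genes Hist1h2ap (-1.16), Hist1h2ac (-1.29) and Hist1h3b (-1.11) have near-identical copies and are uncertain.

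RNA of other cells was lower in knockout Treg-like cells: the B-cell list had a median of -2.01, the macrophage list -0.64 and the neutrophil list, with 1 of 3 measured genes lower, -1.04, which turned without doublet removal (1.03) and under the gate (0.018). Ctse reached its highest CPM in B-like cells. The gate on single cells, which selects cells for a Foxp3 UMI, gave -1.09 for Foxp3 and turned Il13 (-1.86), Dapl1 (-0.12) and Hspa1a (2.35). Separate clustering turned Gzmc (3.49), and thinning turned Lamtor3 (0.27) and the type 2 and type 17 list (-0.32) and left the resting list at -0.06.

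**Figure D2:**
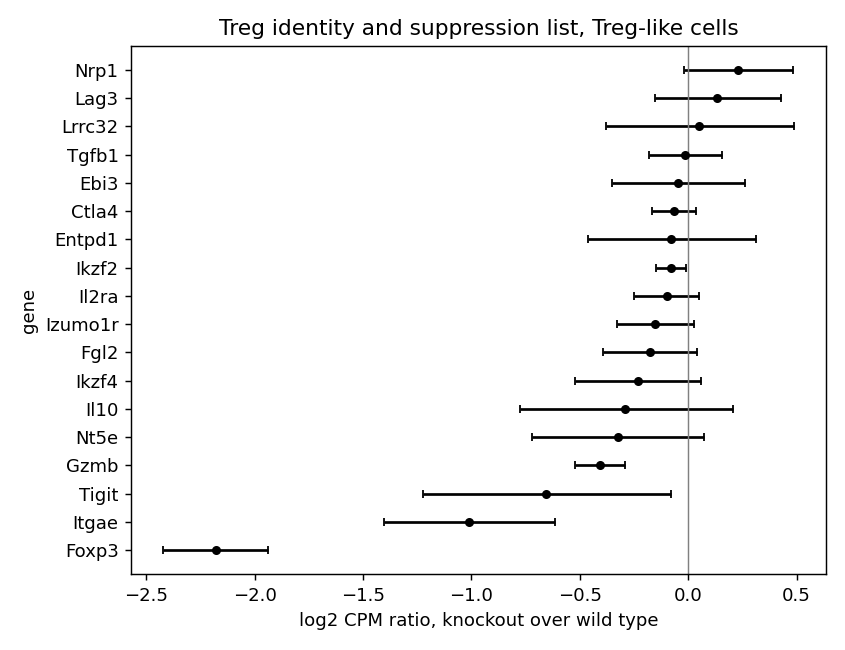
Log2 ratio of knockout over wild-type CPM for measured genes of the Treg identity and suppression list in Treg-like cells, 1 library per genotype; lines are exact 95% counting intervals. Foxp3 at -2.18 lies apart from Il2ra, Ctla4 and Ikzf2, which lie between -0.10 and -0.07.

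In CD8-like cells, 987 wild-type and 1894 knockout cells, with 9217698 and 22400721 UMIs, list medians were below 0 for resting T-cell genes and above 0 for proliferation and biosynthesis. Of 15 resting and central T-cell genes 10 were lower, median -0.65 (percentile 0), among them the follicular chemokine receptor Cxcr5 (-1.07), the tissue egress receptor S1pr1 (-1.03) and Id3 (-1.03). The proliferation list had a median of 0.42 (percentile 100) with 3 of 20 higher, such as Ccnb1 (0.71) and Mcm6 (0.60). Cholesterol and fatty acid synthesis had 4 of 20 higher, median 0.42 (percentile 100), with Idi1 (0.76) and Lss (0.71). Glycolysis had a median of 0.34 (percentile 100) with Hk2, hexokinase 2, higher (0.73), and the unfolded protein response 0.25 (percentile 99.775) with none of 15 past the size rule.

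Among single genes, granzyme A (-1.18 [-1.23, -1.13]) and the receptor Klrg1 (-1.18 [-1.38, -0.97]) were lower, as were Ctse (-1.88 [-2.11, -1.66]), the interferon-inducible Ifi208 (-1.46), Arl5c (-1.27) and Fam241a (-1.24). The serpins Serpina3f (1.58 [1.29, 1.87]), Serpina3g (0.79) and Serpinb9b (0.90) and the interferon-inducible Ifi211 (1.06) were higher. Gzmf was higher (1.19), but 1 cell held 50.4% of its wild-type UMIs, and Tpm3-rs7 (1.86) is uncertain as a near-copy of Tpm3. The cytotoxic effector list, which holds granzyme A and Klrg1, had 2 of 17 genes higher, among them perforin, Prf1 (0.66), and 3 lower, median -0.10 (percentile 1.42), and turned in thinned cells (0.029) and under the gate (0.23). The inhibitory receptor list had a median of 0.09 with none of 17 past the size rule, Pdcd1 at 0.56 and Tox2 at -0.60.

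Thinned shares of CD8-like cells with a Pdcd1 UMI were 9.25% [7.51, 11.2] in the wild-type and 15.9% [14.2, 17.6] in the knockout library, with 3 cells left out of each, and 28.9% and 45.4% unthinned. In B-like cells, which should lack Pdcd1, they were 0.201% and 0.251%, at median depths of 3322 and 3396 UMIs against 5909 and 6604 in CD8-like cells. For Gzmb the thinned shares were 30.1% and 34.1% (unthinned 54.0% and 60.3%, thinned B-like 0.143% and 0.501%). For Ifng they were 18.7% and 20.4% (unthinned 50.1% and 53.2%), and for Mki67 9.55% and 10.9% (unthinned 25.03% and 29.3%). Over all T cells a Cd8a UMI was found in 18.5% and 20.4% of thinned and 41.2% and 41.5% of unthinned cells, against 0.401% of thinned wild-type and no knockout B-like cells.

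Cluster T0, led by Gzmk, held 63.7% of wild-type and 48.5% of knockout CD8-like cells, and cluster T8, led by Serpine2, Lag3 and Havcr2, 14.4% and 20.1%. Cluster T10, led by the interferon-induced Ifit3, Ifit1 and Isg15, held 10.8% and 13.8%. All 7 CD8 markers were detected in T10, but 0 were among its 10 leading genes. Whether T10 also took in interferon-high cells of other T-cell classes, which bears on their type I medians, was not tested. The proliferating clusters T9 and T13, led by Hist1h1b and Cdc20, held 7.60% and 3.44% of wild-type and 11.8% and 5.81% of knockout cells. Without these cells, left out after the data were seen, list medians were 0.43 for proliferation and -0.45 for resting genes, with 1 of 15 higher and 4 lower. Medians were 0.27 for lipid synthesis, 0.29 for glycolysis and 0.11 (percentile 93.8) for the unfolded protein response. Lists of some other cell types were lower in knockout CD8-like cells, with medians of -2.03 for neutrophil, -1.22 for B-cell and -8.14 for erythroid RNA, while the macrophage list stood at -0.10. The erythroid median was much smaller in size without doublet removal. In Treg-like and CD4 conventional-like cells 0 erythroid genes were measured, so erythroid RNA was not spread over all classes. Thinned cells gave a resting list median of -0.31, and separate clustering turned Gzmf (-1.57) and Serpinb9b (-0.99).

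In CD4 conventional-like cells, 537 wild-type and 1059 knockout cells, with 2541487 and 4902888 UMIs, list medians of both interferon responses were above 0. Of 18 type I interferon genes 6 were higher and 0 lower, median 0.43 (percentile 100), with Ifi44 (2.82) and Oasl2 (0.97), and of 19 interferon gamma genes 4 were higher, median 0.28 (percentile 100), with the GTPases Iigp1 (0.73) and Gbp3 (0.64). Tnfrsf4, the co-stimulatory receptor OX40, was higher at 202 against 96.4 CPM (1.06 [0.86, 1.27]). Prelid2 (1.16), the heat shock gene Hspa1b (1.05), Exoc1 (1.10), Got1 (0.87) and Rcbtb2 (0.84) were also higher. Ctse (-1.27 [-1.57, -0.98]) and Selenoi (-1.17) were lower, as were the histone genes Hist1h3c (-2.18), Hist1h2ae (-1.76), Hist1h2ap (-1.40) and Hist1h1d (-1.10), which are a multigene family and uncertain. The resting and central T-cell list had a median of -0.21 (percentile 0) with none of 15 past the size rule, and in the type 1 helper list Il18rap stood at -0.30 and Runx3 at 0.23. Neutrophil RNA had a median of -0.84.

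NK-like cells, 1313 wild-type and 2274 knockout cells, with 8141137 and 12572285 UMIs, had a list median above 0 for cytotoxic effectors. Granzyme B stood at 739 CPM against 368 (1.01 [0.95, 1.07]), and 4 of 17 cytotoxic effector genes were higher and 0 lower, median 0.27 (percentile 100), with Ifng at 0.80 and Gzmc at 1.00. The interferon gamma response had a median of 0.23 (percentile 100) with Cxcl9 (2.18) and Cxcl10 (0.72) higher, glycolysis 0.23 (percentile 100) and the unfolded protein response 0.21 (percentile 99.95) with Asns, asparagine synthetase, higher (0.99). Only 2 of 20 interferon gamma genes passed the size rule. Cxcl9 and Cxcl10 were among the leading genes of cluster 6, of monocyte-like cells, so RNA of those cells stays open as a source of their values. The chemokine Ccl1 was higher (1.19 [1.07, 1.31]), with about the same share of its UMIs, 31.1% and 33.8%, in 1 cell of each library. The leukotriene A4 hydrolase Lta4h (-1.54 [-1.72, -1.35]), Ifi208 (-1.43), Ctse (-1.22 [-1.46, -0.97]), Rpgrip1 (-1.25), the Wnt secretion factor Wls (-0.90 [-1.02, -0.78]) and Hist1h2ap (-0.76) were lower. Some granzyme values rested on single cells: Gzmg had 0 wild-type and 483 knockout UMIs, at least 104-fold higher, with 96.3% of them in 1 cell, and Gzmd (2.66), Gzme (1.67) and Gzmf (3.77) are near-copies of it and uncertain. Tpm3-rs7 stood at 1.83. RNA of some other cell types was lower in the knockout library, with list medians of -1.72 for neutrophil, -0.93 for B-cell and -7.48 for erythroid RNA, while the macrophage list stood at 0.031. Separate clustering turned the cytotoxic list (-0.02), Ccl1 (-1.36), Gzmd (-5.05), Gzme (-6.39) and Gzmg (-2.05), and thinning turned Gzmd (-0.07) and Gzme (-0.79).

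Macrophage-like cells, 824 wild-type and 745 knockout cells, with 23396129 and 12282245 UMIs, had list medians above 0 for interferon-induced, stress and hypoxia genes. Of 19 type I interferon genes 9 were higher and 0 lower, median 0.58 (percentile 100), with Ifi44 (3.19 [2.86, 3.54]) and Ifit2 (1.24). The interferon gamma list had 5 of 20 higher and 2 lower, median 0.30 (percentile 100), with Iigp1 (1.62) and the T-cell attracting chemokine Cxcl9 (1.52) higher and Ciita, the regulator of MHC class II, lower (-0.86). Retnla, a marker of alternative activation, was higher at 134 against 8.29 CPM (4.02 [3.80, 4.24]), as were Rnase2a (4.13), the interferon-inducible GTPase Gbp2b (3.15 [2.81, 3.51]), histidine ammonia lyase Hal (2.71 [2.58, 2.85]) and the activin subunit Inhba (1.70).

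Hypoxia genes had 5 of 14 higher, median 0.43 (percentile 100), led by Adm (1.27) and Egln3 (0.78), glycolysis 2 of 14, median 0.32 (percentile 99.85), with Hk2 (0.98) and the glucose transporter Slc2a1 (0.92), and the AP-1 and dissociation stress list 6 of 18, median 0.39 (percentile 100), led by the heat shock genes Hspb1 (1.67) and Hspa1b (1.48). The inflammatory list had 7 of 16 higher and 1 lower, median 0.33 (percentile 100), with nitric oxide synthase Nos2 (1.63) higher and Il12b lower (-4.25). The alternatively activated list had a median of 0.29 (percentile 99.98) with complement genes C1qa (0.76) and C1qc (0.71) higher. Chemokines had a median of 0.22 (percentile 99.73) and a mean of opposite sign, with Ccl8 higher (1.09) and Ccl22 (-4.99) and Ccl17 (-2.10) lower, and checkpoint ligands a median of 0.28 (percentile 99.88) and likewise a mean of opposite sign, with Cd274, which encodes PD-L1, higher (0.89) and Il4i1 lower (-3.91). Ccl22, Il4i1 and Il12b were among the leading genes of cluster 22, of mature DC-like cells, as were Ccr7 and Tbc1d4, which were lower with them. MHC class II genes had 4 of 10 lower, median -0.34 (percentile 0.02), led by H2-Ob (-2.98) and H2-Oa (-2.91). These 2 genes stood at 20.5 and 20.2 CPM in wild-type macrophage-like cells, against 449 and 212 in B-like cells, and B-cell RNA was lower in the same class, so RNA of B-like and mature DC-like cells stays open as a source of these lower values. Medians were also below 0 for proliferation, -0.27 (percentile 0.03) with Rrm2 at -0.55, for lipid synthesis, -0.26 (percentile 1.78) with the desaturase Scd1 lower (-2.66), and for NF-kB targets, -0.19 (percentile 2.14) with Relb at -0.52.

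Sept3 (-3.68), Ccr7 (-2.68), Tbc1d4 (-2.18) and Wdfy4 (-2.04), genes that were highest in DC-like or B-like cells, and the platelet chemokine Ppbp (-3.21) were lower, while 68.2% of the wild-type UMIs of the melanoma gene Dct (-3.44) came from 1 cell. RNA of other cells was lower in knockout macrophage-like cells, with list medians of -0.75 for T-cell, -2.27 for B-cell, -3.69 for neutrophil and -2.45 for melanoma RNA, while the erythroid list had a median of 1.27. T-cell (0.063) and erythroid RNA (-0.073) turned without doublet removal, and melanoma RNA with looser cell filters (1.12). The T-cell median was also much smaller in size under a common doublet rule, so its main value depended on the unequal doublet removal. Erythroid RNA also turned at resolution 0.5, and melanoma RNA with the listed genes left out of clustering. Median depth was 22263 UMIs in wild-type and 10373 in knockout cells, and the median ratio over all measured genes was -0.12, a shift that the random lists share. Different clusters held most of the class: cluster 11, led by Ccl8, C1qa and C1qc, held 53.3% of wild-type and 33.0% of knockout cells, and cluster 8, led by Mmp12, Inhba and Thbs1, 46.7% and 67.0%. Cluster 11 was the deeper, at a median of 30086 UMIs against 9432.5 in cluster 8. Doublet removal and cell filters kept 94.3% of wild-type but 80.0% of knockout UMIs. The depth difference and the cluster split may thus come in part from unequal doublet removal, which was not tested. Clustering without the listed genes turned the stress list (-0.11), proliferation (0.095), the inflammatory list (-0.35), the checkpoint ligands (-0.05) and Inhba (-1.76). No doublet removal turned the chemokines (-0.05), the alternatively activated list (-0.19) and NF-kB targets. It also left MHC class II, proliferation and lipid synthesis with only slightly negative medians. Separate clustering turned MHC class II (0.66), NF-kB targets (0.22), lipid synthesis (0.43) and the alternatively activated list (-0.50). Under 1 common doublet rule NF-kB targets and the alternatively activated list turned. Resolution 0.5 turned lipid synthesis and the alternatively activated list, thinning turned NF-kB targets, and means of per-cell CPM turned the alternatively activated list.

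Monocyte-like cells, 687 wild-type and 999 knockout cells, with 8562839 and 9980160 UMIs, had higher interferon-induced RNA in the knockout library. Of 20 interferon gamma genes 15 were higher and 0 lower, median 0.80 (percentile 100), with Iigp1 (1.95 [1.74, 2.18]), Cxcl9 at 940.4 against 345 CPM (1.45 [1.39, 1.51]), Cxcl10 (1.30) and Socs1 (1.11). Of 19 type I interferon genes 9 were higher, median 0.56 (percentile 100), with Ifi44 (4.16) and Rsad2 (1.51). Ifi44l had 0 wild-type and 353 knockout UMIs, at least 101-fold higher, and Gbp2b stood at 4.65 [4.23, 5.10]. Gbp2b, Ifi44 and Ifi44l lie on chromosome 3 between 142594847 and 151762892. Whether a linked segment of another strain shifts these genes was not tested. The inflammatory list had 6 of 15 higher and 1 lower, median 0.38 (percentile 100), with Nos2 (1.80) higher and Il23a lower (-1.29), MHC class I a median of 0.34 (percentile 100) with the peptide transporter Tap1 higher (0.66), checkpoint ligands 0.29 (percentile 99.9) with Cd274 (1.10) higher, and NF-kB targets 0.19 (percentile 99.9) with Icam1 (0.70) higher.

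Of 18 alternatively activated and tumour-associated macrophage genes 4 were lower, median -0.20 (percentile 0), among them osteopontin, Spp1 (-1.50), Il10 (-1.49) and arginase, Arg1 (-1.20). The platelet chemokines Ppbp (-4.18 [-4.84, -3.58]) and Pf4 (-2.43 [-2.59, -2.26]), Saa3 (-3.30), Cxcl1 (-2.18) and Prtn3 (-1.94) were lower, as was Ifng (-3.48), with 79.7% of its wild-type UMIs in 1 cell. Proliferation genes had 5 of 19 higher, median 0.31 (percentile 99.98), with Ccnb2 at 2.41, and Tpm3-rs7 stood at 2.54. Lists of other cells had medians of -0.75 for T-cell, -1.70 for neutrophil, -1.33 for B-cell and -7.74 for erythroid RNA. The T-cell median was smaller in size without doublet removal and under a common doublet rule, so it depended in part on the unequal removal. Cluster 6, led by Cxcl9, Vcan and Cxcl10, held 64.5% of wild-type and 74.5% of knockout cells. At resolution 0.5, where monocyte-like cells were grouped more coarsely, the interferon gamma median was 0.21, the type I median 0.12, and Iigp1 (-0.995), Cxcl9 (-0.03), Ppbp (1.85), the NF-kB list (-0.07) and the alternatively activated list (0.05) turned direction. The proliferation list turned in thinned cells (-0.068), in separate clustering (-1.93), with looser (-0.019) and stricter cell filters (-0.035), without doublet removal (-0.055) and with listed genes left out of clustering (-0.19).

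Dendritic (DC-like) cells, 847 wild-type and 812 knockout cells, with 13042045 and 10858509 UMIs, had list medians above 0 for both interferon responses. Of 19 type I interferon genes 10 were higher and 0 lower, median 0.61 (percentile 100), with Ifi44 (2.39 [2.12, 2.65]) and Rsad2 (1.33), and of 20 interferon gamma genes 12 were higher, median 0.63 (percentile 100), with Cxcl9 (1.73 [1.63, 1.82]), Cxcl10 (1.46) and Gbp2 (1.24). The inflammatory list had 6 of 14 higher and 2 lower, median 0.53 (percentile 100), with Nos2 (-1.50) and Il12b (-0.90) the lower ones. Ccl17, a chemokine for CCR4-bearing T cells, was higher (1.81 [1.64, 1.98]), as were Mtmr9 (1.83 [1.47, 2.20]), Crip2 (1.81) and Tpm3-rs7 (1.87). Lower were Ctse (-1.55 [-1.79, -1.32]), Rpgrip1 (-1.34 [-1.59, -1.10]), the metallothionein Mt2 (-2.17, with 68.0% of wild-type UMIs in 1 cell), Phlda1 (-1.32) and lymphotoxin beta, Ltb (-1.19). Dct (-2.23) rested on 1 wild-type cell with 97.47% of its UMIs there. Lists of other cells were lower, with medians of -0.94 for T-cell, -1.55 for B-cell, -1.90 for neutrophil, -1.85 for melanoma and -6.40 for erythroid RNA, and subtracting free RNA turned Ltb to 0.94. Without doublet removal the T-cell (0.25) and erythroid lists (0.19) turned, and the melanoma list turned with listed genes left out of clustering (2.66), under 1 doublet rule (0.42) and with means of per-cell CPM (0.069). The T-cell median was also smaller in size under 1 doublet rule, so its main value depended on the unequal doublet removal. Within the class, cluster 10 (cDC2-like) held 38.3% of wild-type and 49.9% of knockout cells and cluster 16 (pDC-like) 27.9% and 16.6%.

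B-like cells, 3507 wild-type and 401 knockout cells, with 12255051 and 1533983 UMIs, had the highest interferon gamma list median of the 8 classes under the main settings, 1.03 (percentile 100). With separate clustering the median of monocyte-like cells was higher. In B-like cells 14 of 20 genes were higher and 0 lower in the knockout library, among them Iigp1 (3.00), Gbp2 (2.03) and Socs1 (1.68). The type I list had a median of 0.38 (percentile 99.95) with 2 of 17 higher, Zbp1 (0.99) and Isg20 (0.89), MHC class I 0.23 (percentile 99.86) with its regulator Nlrc5 higher (1.00), and glycolysis 0.35 (percentile 99.99) with Hk2 at 0.92. The chemokine receptor Cxcr3 (3.40 [2.65, 4.16]), Serpina3f (3.28 [2.69, 3.87]), Prelid2 (3.40), Aldh7a1 (2.42), the transcription factor Bhlhe41 (2.09 [1.63, 2.53]) and Ahnak (1.49) were higher. Ctse (-1.29 [-1.66, -0.95]), the coenzyme Q kinase Coq8a (-1.76), Il12a (-1.38), Ifi208 (-1.70), the integrin Itgb3 (-1.60) and Hist1h2ap (-1.41) were lower. T-cell RNA was higher in knockout B-like cells, median 0.87, and neutrophil (-1.28) and erythroid RNA (-6.45) lower. With mitochondrial shares of at most 5% the interferon gamma median was 0.66 and T-cell RNA turned to -0.54, as it did without doublet removal, to -0.16.

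**Figure D3:**
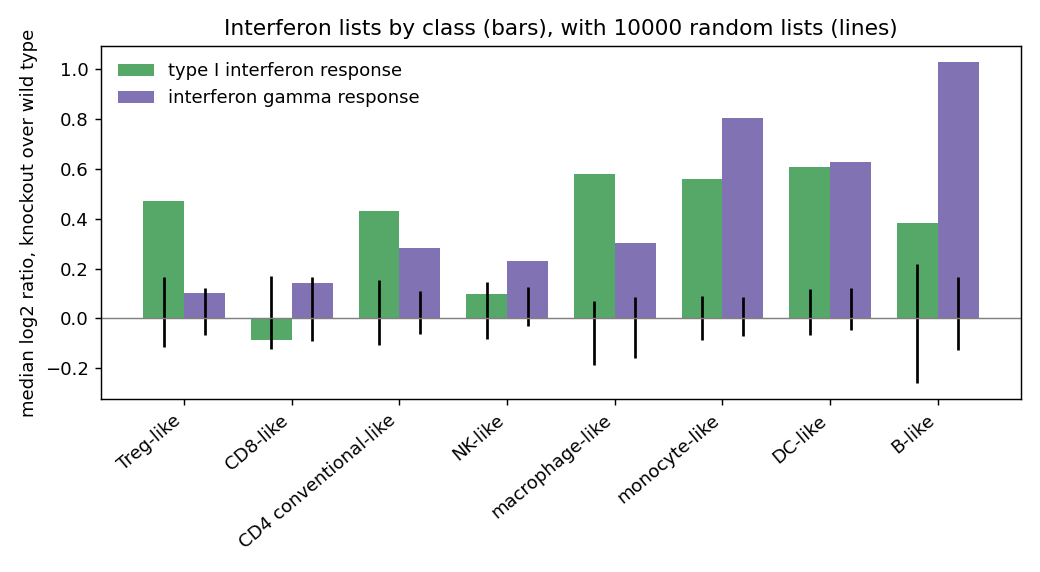
Median log2 ratio of knockout over wild-type CPM of the type I interferon and interferon gamma lists in the 8 compared classes (bars), with the middle 95% of 10000 random lists matched on expression (lines). The interferon gamma median runs from 0.10 in Treg-like to 1.03 in B-like cells, and the type I median from -0.09 in CD8-like to 0.61 in DC-like cells.

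Lists with small medians ran over narrow ranges across the classes compared. Apoptosis and p53 genes ran from 0.00 in macrophage-like to 0.20 in CD8-like cells, with Cdkn1a at 0.53 in CD8-like cells and Mcl1 at 0.59 in macrophage-like cells. Mitochondrial-encoded oxidative phosphorylation genes ran from -0.14 in DC-like to 0.09 in Treg-like cells, nuclear-encoded ones from -0.06 in monocyte-like to 0.12 in CD8-like cells, and sex-linked genes from -0.20 in macrophage-like to 0.15 in NK-like cells, where Ddx3y, Uty and Kdm5d had UMIs in both libraries. The type 1 helper list ran from 0.00 in CD4 conventional-like to 0.03 in Treg-like cells. Neutrophil-like cells, 240 wild-type and 37 knockout, were too few to compare.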

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

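Added after the data were seen were 1 doublet rule for both libraries, shares over cells other than B-like, naive T-like and pDC-like, and CD8-like, naive T-like and gamma-delta-like cells without cells in doubt; all other alternatives were planned. Direction was kept under every alternative that gave a value for the lower Foxp3 of Treg-like cells (-2.65 to -1.09), for the lower B-like share (-3.25 to -2.82), and for the higher CD8-like (0.38 to 1.00), NK-like (0.24 to 0.88) and Treg-like shares (0.16 to 1.55). The interferon gamma median kept its direction in B-like (0.66 to 1.07), monocyte-like (0.21 to 1.41) and DC-like cells (0.42 to 0.93), and the type I median in Treg-like cells (0.26 to 0.60). Of 1656 values of named genes under the alternatives, 1330 stayed within their counting interval, 302 moved beyond it and 24 turned direction; of 1340 reported list medians 1045 stayed within the spread of their random lists, 245 moved and 50 turned. For 93 further medians, given only through their range or not at all, 33 of 1401 values turned. CPM without mitochondrial and ribosomal protein genes turned or moved none of the values that follow. The alternative of unthinned cells applies to shares of cells with a UMI, since class shares use unthinned cells throughout. Free RNA was estimated at 48.5% and 37.5% of UMIs in wild-type and knockout macrophage-like cells and 31.4% and 8.84% in DC-like cells, where the subtraction is coarse. Depth limits B-like cells most, with 1533983 knockout UMIs. No paired analysis was possible because each genotype has 1 library.

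Values that moved or turned are log2 ratios, for a list its median and for a gene its own ratio; the cause was not tested, except that the gate selects cells on Foxp3 and a smaller denominator changes every share by construction. Free RNA is scaled on the genes of other cell types, so the values of their lists after subtraction are remainders and test no direction. With 200 genes and 500 UMIs, the log2 ratio of shares was -1.10 for pDC-like. Treg-like cells gave 0.16 for type 1 helper and -2.21 for neutrophil RNA. CD8-like cells gave -3.21 for B-cell RNA and -9.06 for erythroid RNA. CD4 conventional-like cells gave 0.27 for type I interferon and -1.75 for neutrophil RNA. Macrophage-like cells gave 1.27 for Dct, 0.42 for type I interferon, 0.61 for hypoxia and 1.12 for melanoma RNA. Monocyte-like cells gave -0.019 for proliferation and -1.26 for T cell RNA. DC-like cells gave 0.51 for interferon gamma, -0.31 for melanoma RNA, -1.23 for T cell RNA and -2.01 for B-cell RNA. B-like cells gave 0.31 for T cell RNA. At a mitochondrial share of at most 5%, log2 ratios of shares were -3.25 for B-like, 0.82 for CD8-like, 0.77 for NK-like, 0.24 for gamma-delta-like, 0.45 for monocyte-like, -1.16 for pDC-like and 0.18 for monocyte/macrophage. CD8-like cells gave -2.47 for erythroid RNA. In CD4 conventional-like cells values were -1.55 for neutrophil RNA. NK-like cells gave 0.18 for cytotoxic effector. Macrophage-like cells gave -0.46 for proliferation, -0.42 for lipid synthesis, 0.54 for inflammatory, -2.99 for neutrophil RNA, -1.07 for T cell RNA and -1.46 for B-cell RNA. Monocyte-like cells gave -0.035 for proliferation, -0.97 for T cell RNA, -2.83 for B-cell RNA and -7.46 for erythroid RNA. DC-like cells gave -2.32 for neutrophil RNA and -2.00 for B-cell RNA. B-like cells gave 0.15 for type I interferon, 0.66 for interferon gamma, -0.54 for T cell RNA and -7.02 for erythroid RNA. Without doublet removal, log2 ratios of shares were 0.44 for macrophage-like and 0.55 for monocyte/macrophage. Treg-like cells gave 1.03 for neutrophil RNA and -0.20 for macrophage RNA. CD8-like cells gave -2.35 for erythroid RNA. CD4 conventional-like cells gave -1.93 for neutrophil RNA. Macrophage-like cells gave 0.018 for NF-kB, 0.56 for interferon gamma, -0.024 for MHC class II, -0.065 for proliferation, -0.024 for lipid synthesis, -0.048 for chemokines, -0.19 for alternatively activated, -0.31 for melanoma RNA, -1.46 for neutrophil RNA, 0.063 for T cell RNA and -0.073 for erythroid RNA. Monocyte-like cells gave -0.055 for proliferation and -0.17 for T cell RNA. DC-like cells gave 0.41 for type I interferon, 0.31 for inflammatory, -3.60 for melanoma RNA, -0.83 for neutrophil RNA, 0.25 for T cell RNA, -1.10 for B-cell RNA and 0.19 for erythroid RNA. B-like cells gave 0.86 for interferon gamma, -0.16 for T cell RNA and -6.14 for erythroid RNA. At resolution 2, the log2 ratio of shares was 0.91 for CD8-like. CD8-like cells gave -2.43 for erythroid RNA. In CD4 conventional-like cells values were -1.75 for neutrophil RNA. NK-like cells gave 0.16 for cytotoxic effector. At resolution 0.5, log2 ratios of shares were 0.34 for macrophage-like, 0.13 for monocyte-like and -1.16 for pDC-like. Treg-like cells gave -2.12 for neutrophil RNA. CD8-like cells gave -2.99 for B-cell RNA. CD4 conventional-like cells gave -1.64 for neutrophil RNA. Macrophage-like cells gave -0.0022 for NF-kB, 0.77 for type I interferon, 0.79 for interferon gamma, -0.077 for MHC class II, -0.59 for proliferation, 0.21 for hypoxia, 0.049 for lipid synthesis, 0.53 for inflammatory, -0.085 for alternatively activated, -1.42 for B-cell RNA and -0.48 for erythroid RNA. Monocyte-like cells gave -0.995 for Iigp1, -0.029 for Cxcl9, 1.85 for Ppbp, -0.071 for NF-kB, 0.12 for type I interferon, 0.21 for interferon gamma, 0.038 for MHC class I, 0.060 for inflammatory, 0.048 for alternatively activated, -1.29 for neutrophil RNA, -1.87 for T cell RNA and -3.36 for B-cell RNA. DC-like cells gave 0.54 for interferon gamma and -1.25 for T cell RNA. With separate clustering, log2 ratios of shares were -2.82 for B-like, 0.60 for CD8-like, 1.55 for Treg-like, 2.54 for macrophage-like, -0.87 for monocyte-like, -0.59 for cDC1-like, -0.15 for DC-like, 0.96 for Treg-like share of T cells and -0.95 for CD8-like per Treg-like. Treg-like cells gave 3.49 for Gzmc, -2.65 for Foxp3, -0.41 for Treg identity, 0.38 for type 1 helper, 0.28 for inhibitory receptors, 0.26 for type I interferon and -5.11 for B-cell RNA. CD8-like cells gave -1.57 for Gzmf, -0.99 for Serpinb9b, -0.43 for resting T cell, -0.20 for inhibitory receptors, 0.54 for proliferation, -2.85 for B-cell RNA and -7.63 for erythroid RNA. In CD4 conventional-like cells values were -0.075 for resting T cell and -1.60 for neutrophil RNA. NK-like cells gave -2.05 for Gzmg, -5.05 for Gzmd, -6.39 for Gzme, -1.36 for Ccl1, -0.022 for cytotoxic effector and 0.021 for glycolysis. Macrophage-like cells gave 0.66 for stress, 0.22 for NF-kB, 1.09 for type I interferon, 0.86 for interferon gamma, 0.66 for MHC class II, -0.90 for proliferation, 0.49 for glycolysis, 0.76 for hypoxia, 0.43 for lipid synthesis, 0.68 for chemokines, 1.16 for inflammatory, -0.50 for alternatively activated, 0.57 for checkpoint ligands, -3.95 for melanoma RNA, -2.39 for neutrophil RNA, -1.73 for B-cell RNA and 3.58 for erythroid RNA. Monocyte-like cells gave 0.0048 for NF-kB, 1.16 for type I interferon, 1.41 for interferon gamma, -1.93 for proliferation, -0.13 for nuclear-encoded phosphorylation, 0.54 for inflammatory, -2.49 for alternatively activated, -2.85 for T cell RNA, -2.61 for B-cell RNA and -6.94 for erythroid RNA. DC-like cells gave 0.78 for type I interferon, 0.42 for interferon gamma, -1.60 for T cell RNA and -6.00 for erythroid RNA. With listed genes left out of clustering, the log2 ratio of shares was -0.85 for macrophage-like. CD8-like cells gave -3.42 for B-cell RNA and -10.13 for erythroid RNA. Macrophage-like cells gave -1.76 for Inhba, -0.11 for stress, -0.46 for NF-kB, 0.16 for type I interferon, -0.67 for MHC class II, 0.095 for proliferation, 0.22 for hypoxia, -0.20 for apoptosis, -0.35 for inflammatory, -0.053 for checkpoint ligands, 0.28 for melanoma RNA, -2.62 for neutrophil RNA, -1.10 for B-cell RNA and 1.70 for erythroid RNA. Monocyte-like cells gave 0.73 for interferon gamma, -0.19 for proliferation, -0.68 for neutrophil RNA and -1.62 for erythroid RNA. DC-like cells gave 2.92 for Dct and 2.66 for melanoma RNA. Under the single-cell gate, log2 ratios of shares were 0.61 for CD8-like, 0.16 for Treg-like, -0.51 for Treg-like share of T cells and 0.45 for CD8-like per Treg-like. Treg-like cells gave -1.86 for Il13, -0.12 for Dapl1, -1.09 for Foxp3, 2.35 for Hspa1a, -0.0026 for Treg identity, 0.11 for effector Treg, 0.78 for type 2 and type 17 helper, 0.12 for inhibitory receptors, 0.10 for lipid synthesis, 0.018 for neutrophil RNA and -1.48 for B-cell RNA. CD8-like cells gave -0.93 for resting T cell, 0.23 for cytotoxic effector, 0.43 for inhibitory receptors, 0.74 for proliferation, 0.58 for glycolysis, 0.28 for nuclear-encoded phosphorylation, 0.62 for lipid synthesis, 0.42 for unfolded protein and -7.62 for erythroid RNA. Under 1 doublet rule, log2 ratios of shares were 0.36 for macrophage-like, 0.66 for cDC2-like, 0.55 for monocyte/macrophage and 0.18 for DC-like. Treg-like cells gave -2.94 for neutrophil RNA, -1.86 for macrophage RNA and -1.26 for B-cell RNA. CD8-like cells gave -2.51 for erythroid RNA. Macrophage-like cells gave 0.012 for NF-kB, 0.64 for interferon gamma, 0.24 for hypoxia, 0.23 for apoptosis, 0.58 for inflammatory, -0.0073 for alternatively activated, -3.18 for melanoma RNA, -1.12 for neutrophil RNA, -0.068 for T cell RNA and 1.86 for erythroid RNA. Monocyte-like cells gave -0.52 for T cell RNA and -6.76 for erythroid RNA. DC-like cells gave 0.42 for Dct, 0.78 for interferon gamma, 0.36 for inflammatory, 0.42 for melanoma RNA, -1.45 for neutrophil RNA, -0.29 for T cell RNA and -2.00 for erythroid RNA. Over cells other than B-like, naive T-like and pDC-like, log2 ratios of shares were 0.42 for CD4 conventional-like, 0.38 for CD8-like, 0.24 for NK-like, 0.54 for Treg-like, -0.22 for gamma-delta-like, -0.70 for macrophage-like, -0.016 for monocyte-like, -0.56 for cDC1-like, -0.23 for cDC2-like, -0.85 for mature DC-like, -3.25 for neutrophil-like and -0.35 for monocyte/macrophage. In thinned cells, Treg-like cells gave 0.27 for Lamtor3, -0.059 for resting T cell, -0.32 for type 2 and type 17 helper and -0.82 for B-cell RNA. CD8-like cells gave -0.31 for resting T cell, 0.029 for cytotoxic effector, 0.28 for inhibitory receptors, -0.72 for neutrophil RNA and -0.55 for B-cell RNA. NK-like cells gave -0.075 for Gzmd, -0.79 for Gzme, 0.14 for interferon gamma, -0.72 for neutrophil RNA, -0.15 for B-cell RNA and -6.22 for erythroid RNA. Macrophage-like cells gave 0.050 for NF-kB, -0.063 for MHC class II, -0.55 for proliferation, -0.087 for lipid synthesis, 0.70 for inflammatory, 0.23 for sex-linked, -1.34 for neutrophil RNA, -1.16 for T cell RNA and -3.46 for B-cell RNA. Monocyte-like cells gave 0.66 for type I interferon, -0.068 for proliferation, 0.62 for inflammatory, -2.22 for neutrophil RNA and -6.80 for erythroid RNA. DC-like cells gave 1.06 for Dct, 0.70 for inflammatory, -0.25 for neutrophil RNA and -4.67 for erythroid RNA. B-like cells gave -4.80 for erythroid RNA. With means of per-cell CPM, Treg-like cells gave 0.16 for type 1 helper, 0.092 for type 2 and type 17 helper, 0.13 for T-cell receptor response and -0.70 for B-cell RNA. CD8-like cells gave -0.36 for resting T cell. NK-like cells gave -0.27 for Gzme and -6.81 for erythroid RNA. Macrophage-like cells gave -0.018 for NF-kB, -0.073 for MHC class II, -0.65 for proliferation, 0.070 for chemokines, 0.59 for inflammatory, -0.045 for alternatively activated, -1.63 for melanoma RNA, -2.76 for neutrophil RNA and -1.23 for T cell RNA. Monocyte-like cells gave 0.88 for interferon gamma and -7.35 for erythroid RNA. DC-like cells gave 0.050 for Dct, 0.76 for interferon gamma, 0.069 for melanoma RNA and -5.59 for erythroid RNA. B-like cells gave 0.88 for interferon gamma and -5.15 for erythroid RNA. With free RNA subtracted, Treg-like cells gave -0.84 for B-cell RNA. CD8-like cells gave -9.84 for erythroid RNA. NK-like cells gave -8.56 for erythroid RNA. Macrophage-like cells gave 0.16 for interferon gamma, -0.13 for MHC class II, -0.72 for proliferation, -0.62 for lipid synthesis, 0.52 for inflammatory, 0.15 for alternatively activated, -3.19 for melanoma RNA, 0.15 for neutrophil RNA, -9.03 for T cell RNA, 5.20 for B-cell RNA and 9.22 for erythroid RNA. Monocyte-like cells gave 0.44 for MHC class I, 0.58 for proliferation, -0.37 for neutrophil RNA, -2.94 for T cell RNA, 5.68 for B-cell RNA and -9.16 for erythroid RNA. DC-like cells gave 0.94 for Ltb, 0.93 for interferon gamma, 0.67 for inflammatory, 0.76 for neutrophil RNA, -0.28 for T cell RNA, 0.16 for B-cell RNA and -7.55 for erythroid RNA. B-like cells gave -7.20 for erythroid RNA. From 100 UMIs, Treg-like cells gave 0.13 for type 2 and type 17 helper and -0.79 for B-cell RNA. CD8-like cells gave -0.61 for B-cell RNA. NK-like cells gave -0.85 for neutrophil RNA and -0.38 for B-cell RNA. Macrophage-like cells gave -1.87 for neutrophil RNA and -3.33 for B-cell RNA. DC-like cells gave -0.29 for neutrophil RNA, -2.69 for B-cell RNA and -6.94 for erythroid RNA. With no minimum, Treg-like cells gave -1.13 for B-cell RNA. CD4 conventional-like cells gave -2.63 for neutrophil RNA. NK-like cells gave -0.85 for neutrophil RNA. Monocyte-like cells gave -0.82 for neutrophil RNA. DC-like cells gave -1.31 for neutrophil RNA. With TMM factors, macrophage-like cells gave 0.43 for interferon gamma and -0.14 for proliferation. Without the melanoma-bearing cell, naive T-like cells gave 0.19 for glycolysis, -0.012 for proliferation and 0.070 for lipid synthesis. Without reassigned proliferating cells, CD8-like cells gave -0.45 for resting T cell and 0.27 for lipid synthesis. Gamma-delta-like cells gave 0.38 for proliferation. In unthinned cells, the log2 ratio of shares was -1.02 for share of Treg-like cells with a Foxp3 UMI.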

Other observations

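Comparisons of gamma-delta-like and naive T-like cells with and without cells in doubt, and the tests of dilution, of unequal doublet removal, of linked segments and of genes shifted in at least 6 of the 8 classes, were chosen only after the results were seen. In gamma-delta-like cells, 703 wild-type and 889 knockout, 7 of 18 measured interferon gamma genes were higher in the knockout library and 0 lower, median 0.50 (percentile 100), led by Iigp1 (1.93). Of 19 type I genes 6 were higher, median 0.45 (percentile 100). Without the 11 wild-type and 6 knockout proliferating cells reassigned to this class these medians were 0.45 and 0.42. The proliferation list had 7 of 20 genes lower, median -0.33 (percentile 0), but without those cells its median was 0.38 with 0 of 18 lower, so its direction rested on them. Erythroid RNA had a median of -9.48 in gamma-delta-like cells.

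In naive T-like cells, 702 wild-type and 365 knockout, Ctse (-1.62) and the activation-induced Nr4a1 (-1.23) were lower in the knockout library. Values above 0 for glycolysis (0.58), proliferation (0.45) and lipid synthesis (0.44) rested wholly or in part on 1 knockout cell that held 98.9% of the UMIs of the melanoma gene Pmel. Without this cell the medians were 0.19 (percentile 99.95), -0.012 and 0.070, with 0 of 14 glycolysis genes past the size rule.

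Foxp3 was lower in knockout Treg-like cells (-2.18) than in wild-type ones. The other 8 preset Treg markers had a median log2 ratio of -0.072, single markers lying between -0.15 and 0.27. Among them Ccr8 had a wide interval (0.21 [-0.79, 1.31]). Dilution of the class by other T cells would lower these markers with Foxp3. They also served to name the class and to place its proliferating cells, so they argue against dilution only in part. Thinning to 1 depth left Foxp3 at -1.99 [-2.51, -1.49], so the deepest cells did not set the ratio. CPM was already scaled to the class total, and thinning keeps the expected proportions within a cell. The thinned ratio could thus hardly have come near the range written for depth, and it decides little about depth. Median depths were 6126 wild-type and 5834 knockout UMIs. Of knockout Treg-like cells 26.3% held a Foxp3 UMI, within the 21.1% to 28.1% that an even lowering of the wild-type level would give, which argues against a full loss in only part of the cells. A hypothesis, on which these 3 tests bear only in part, is that the knockout may lower Foxp3 RNA across the Treg-like cells, in which Itgae (-1.01) and Tigit (-0.66) of the wider identity list were also lower; with 1 library per genotype a difference between the mice or preparations cannot be separated from genotype. The count reads the 3' end of Foxp3, so an altered allele or transcript end stays open and was not tested.

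B-like and naive T-like cells took smaller shares of the knockout library. With the same doublet rule in both libraries the B-like log2 share ratio was -3.11 [-3.27, -2.97]. The knockout library already used this rule, so only wild-type cells changed. It removes 9.15% of wild-type cells, too few to bring a B-like share of 32.7% near the 3.96% of the knockout library. The outcome was thus set in advance and is no separate evidence on unequal doublet removal. Resting lymphoid or blood B cells admixed to the wild-type library could lower resting B genes in the knockout class: 5 preset genes of this kind, among them Ighd (-0.46) and Ccr7 (-0.08), had a median of -0.35, below 0 but short of the 1.5-fold set in advance, so the test decides neither way. Genotype stays open and was not tested apart from the library.

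Some genes shifted in 1 direction across classes. Ctse and Hist1h2ap were at least 1.5-fold lower and Cxcl10 higher in all 8 classes, of 6861 genes measured in each; 0% of these 3 stayed so in all classes after free RNA was subtracted and 0 pairs lay within 10 Mb, but 3 genes are too few to decide. In at least 6 of 8 classes, 13 of 8207 genes shifted, 6 higher and 7 lower, among them Ctse (chromosome 1, 131638306 to 131675505), Ifi208, Rpgrip1, Mtmr9 and Tpm3-rs7, and 9 of them (69.2%) kept this after free RNA was subtracted, between the bounds set for and against free RNA. A segment of another strain carried with the knockout allele might shift linked genes: 1 pair of genes with different symbol stems, Lamtor3 and Gbp2b, lay within 10 Mb, with Ifi208 and Ifi211 left out as 1 family, and random sets counted the same way had a median of 1 (middle 95% 0 to 3), so the bound written for rejecting it, a count at or below the median, was too lax to decide and was tightened after the value was seen. Xkr6 (chromosome 14, 63606503 to 63820809), a neighbour of Mtmr9 (chromosome 14, 63519651 to 63543982), was higher in 5 of 5 compared classes with enough UMIs (1.53 to 3.27) and in gamma-delta-like cells (3.87). It was chosen because of these values, so it goes with this explanation by choice and tests nothing. Chromosome 14 held 3 of the 13 shifted and 290 of the 8207 measured genes, and chromosome 1 held 3 and 478. Mcub and Lamtor3, which were lower, and Gbp2b, Ifi44 and Ifi44l, which were higher, lay between 129914960 and 151762892 on chromosome 3. This stretch was picked after the values were seen and was not tested, and the explanation stays open.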
